A study of Mus musculus with 4 samples.

How the data were processed

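The data were RNA sequencing of 4 libraries of LPS-treated mouse BV-2 cells, 2 controls and 2 with SIX2 knockdown, grouped by the labels. Per the labels' protocols, mRNA was captured with oligo-dT beads, libraries were made with a dUTP strand-marking kit and sequenced paired-end on a NovaSeq instrument. The deposited values were estimated counts, whole numbers per Ensembl gene that were not normalised; per the submitters' processing notes Bowtie 0.12.2 and genome build mm8 were named, and the counting program is not given in the sources used here. The deposited FPKM values, named so per the file headers, were fragments scaled by the authors to gene length and library total, with no further step stated. The counts were already whole, so rounding changed nothing. Their low values peaked at multiples of 4 (42.1% to 47.2% of values from 1 to 20), so 1 fragment was taken as about 4 counts and the floor as 3 fragments, or 12 counts. Despite the build named, 21876 of 24422 genes (89.6%) had coordinates identical to GENCODE M21 on GRCm38, and coordinates are given on that build. There were 55401 genes with counts and 24473 with FPKM values, and the 4 count columns were identical in both. Another 12 columns, which match no labelled sample, were not used. Whether counting used the strand is not stated.

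The libraries held 75.7, 61.0, 74.7 and 64.3 M counts (control 1 and 2, knockdown 1 and 2), so a floor of 12 counts stood for 0.159, 0.197, 0.161 and 0.187 CPM. Between the replicates of a group the chi-square per degree of freedom, in fragments, was 20.4 for control and 21.0 for knockdown, well above counting error. Intervals and floors given here cover counting error only.

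Genes were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr by group, TMM scaling, a quasi-likelihood fit with the robust option and a two-sided F test, with Benjamini-Hochberg adjusted p under 0.05. Fold changes are knockdown minus control on the log2 scale with SE from the fit, and CPM are TMM-scaled, given as mean ± SD. No covariate was used. The 35 gene lists were tested, where at least 5 members were tested (33 lists), by camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), adjusted over those lists, with an estimated correlation and the fry test beside it. GO and KEGG terms in the deposited annotation with 10 to 500 tested genes were tested by the one-sided Fisher exact test, higher and lower genes apart, adjusted over terms and directions, against 12250 tested genes with a term.

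Genes were named by a rule fixed in advance. It took Six2 and a panel of 12 polarisation genes; the 8 largest folds in each direction among changed genes with an official symbol, a mean of at least 5 CPM and no overlap between groups; and from each list up to 3 changed members with the lowest adjusted p or, where none passed, up to 2 with the highest CPM. Any changed gene of the sine oculis, EYA and DACH list was to be named as well. A few genes that the rule or the lists would name are not reported here.

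The scripts were tested on simulated counts with 200 genes changed. These were drawn from genes with a mean of at least 5 CPM, so recovery below that level was not tested. With spread following the trend with expression (15103 genes), 31.3%, 74.6% and 98.5% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, and 4 of 144 calls were unchanged genes. With spread estimated gene by gene (15030 genes), the shares were 16.4%, 74.6% and 93.9%, and 21 of 144 calls (14.6%) were unchanged genes. With no change simulated, 0 genes were called under the trend spread and 14 under the gene-by-gene spread.

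The alternatives tried were DESeq2 1.42.0, RLE factors, library totals alone, no filter and a stricter filter on low counts, limma-voom, no robust option, limma-trend on log2 FPKM with 1 or 0.1 added, an adjusted p under 0.01, leaving out each library, and other list and term settings. Counts divided by 4, a newer dispersion method, and leaving out pseudogenes and genes overlapping on the same strand were added after the data were seen.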

Results

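RNA sequencing measured gene expression in 4 libraries from BV-2 cells, an immortalised mouse microglial line used as a model of the brain's resident macrophages. Each library came from cells treated with lipopolysaccharide (LPS), a bacterial cell wall component sensed through TLR4, at 100 ng/mL for 24 h. There were 2 control libraries, labelled wild type, and 2 libraries of cells with a knockdown of SIX2, a homeobox transcription factor of the sine oculis family. The sample titles were sh c1 and sh c2 for control and sh s1 and sh s2 for knockdown. Both groups share the sh prefix, so the wild type label may not mean untreated cells. The series concerns SIX2 in the alternative (M2-type) activation of microglia, vesicle-borne microRNA and dopaminergic neurons in Parkinson's disease, and the only comparison the labels allow was knockdown against control under LPS. The control libraries held 75.7 and 61.0 M counts and the knockdown libraries 74.7 and 64.3 M. At about 4 counts per sequenced fragment, these totals correspond to 15.2 to 18.9 M fragments per library. Nothing in the labels says whether the replicates of a group were separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

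The gene lists, the main test and the rule for the genes named below were fixed before the data were examined. Socs3, Fcgr1, Csf1r, Aif1, Fabp5, Cmpk2, Nfkb2, Tnfaip3, Ykt6, Anxa6, Vps28, Marco, Hp and Saa3 fall outside that rule and were chosen after their values were seen. The same holds for Tlr4, Snap25, Syt1 and Gm6430.

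The targeted gene was checked first. Six2 (ENSMUSG00000024134, chromosome 17, 85684277 to 85688274, minus strand, GRCm38) had a count of 0 in all 4 libraries, controls included. A count of 0 allows up to 12 counts (3 fragments) per library, or 0.159 to 0.197 CPM (counts scaled to the library total), a limit that covers counting error only. Six2 mRNA was not detectable at this depth in either group, so neither the knockdown nor the group labels could be checked on it, and no fold change was given. Of the sine oculis, EYA and DACH family genes, which encode related transcription factors and their cofactors, 5 of 12 listed genes were expressed enough to be tested and 0 changed, over all genes and when adjusted over the list alone. Eya3, the most abundant, had 136 ± 9.04 CPM in control and 134 ± 20.3 CPM in knockdown libraries (SD, n = 2 each). Six5 had 5.15 ± 0.928 and 5.62 ± 0.995 CPM. The list's median log2 fold change was -0.03 and its mean 0.10, and camera placed it lower with an adjusted p of 0.978.

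In the knockdown libraries the complement C1q genes, several LPS-response genes and the growth factor gene Igf1 were lower, while the chemokine gene Ccl6 and the cystatin F gene Cst7 were higher. C1qa, C1qb and C1qc encode the chains of C1q, the starter of the classical complement pathway. They fell by 1.61 ± 0.21, 1.00 ± 0.07 and 1.15 ± 0.08 on the log2 scale (SE, adjusted p = 0.0267, 0.00737 and 0.00646, edgeR with Benjamini-Hochberg adjustment). Nos2, the inducible nitric oxide synthase of activated macrophages, fell from 62.5 ± 9.19 to 25.5 ± 3.08 CPM (SD, n = 2 each), and Igf1 from 94.6 ± 1.18 to 53.7 ± 1.82 CPM. Ccl6 rose from 9.79 ± 0.495 to 28.7 ± 1.63 CPM and Cst7 from 9.26 ± 0.771 to 24.6 ± 2.26 CPM. The C1q genes lie side by side on the minus strand of chromosome 4 (C1qb 136880129 to 136886187, C1qc 136889804 to 136893065 and C1qa 136895917 to 136898803), and Nos2 lies on chromosome 11 (78920787 to 78960254, plus strand).

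Of 15733 genes tested with edgeR's quasi-likelihood test, 150 passed a Benjamini-Hochberg adjusted p of 0.05, 64 higher and 86 lower in knockdown libraries. Of these, 55 differed at least 2-fold, 25 higher and 30 lower. At an unadjusted p of 0.05, 2237 genes (14.2%) passed. The libraries of the groups did not overlap for 47.6% of genes, against 33.3% by chance. The median log2 fold change over all genes was -0.01. The 150 genes kept their direction in all 17 other fits, as far as they were tested there. Those fits reused the libraries that picked the genes, so this was not a separate check. The number of changed genes varied: it was 806 with DESeq2, 297 with no filter on low counts, 65 with limma-voom and 7 without edgeR's robust option. With limma on log2(FPKM + 1) values it was 3, of which 1 was among the 150. Without genes that overlap another gene model on the same strand or are pseudogenes, a choice made after the data were seen, it was 243. In each fit that left out 1 library, and so kept 1 in a group, most of the genes called were not among the 150.

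**Figure D1:**
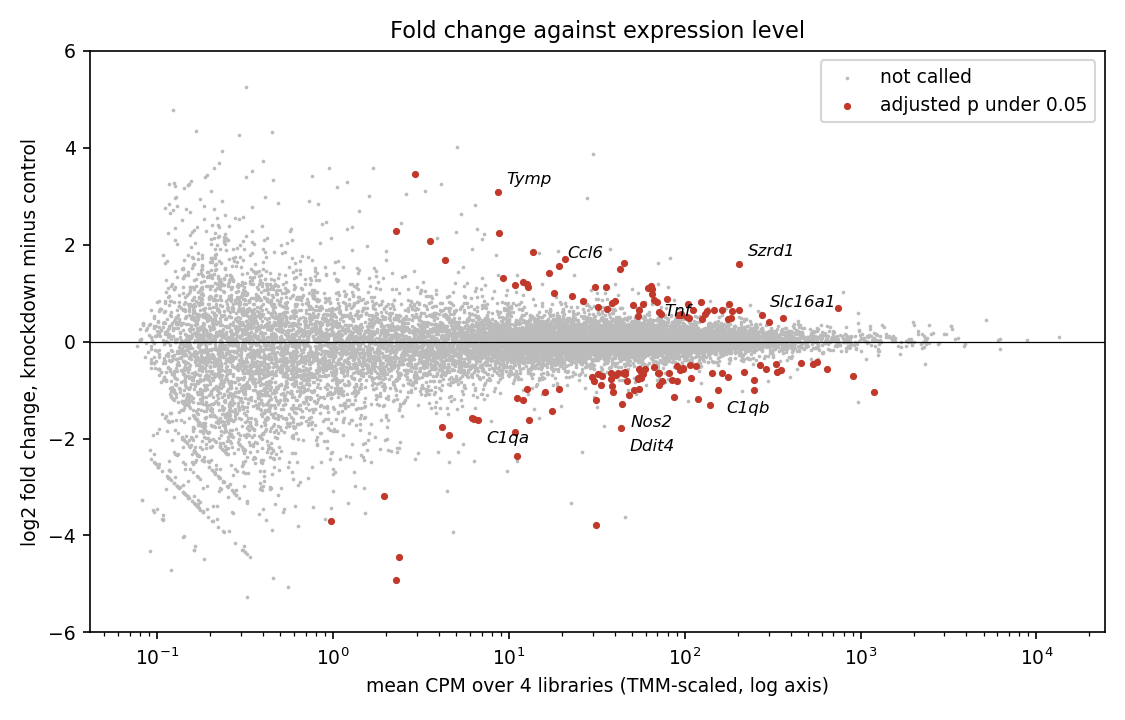
The horizontal axis gives each gene's mean CPM over the 4 libraries (log axis) and the vertical axis its log2 fold change, knockdown minus control. Red points are the 145 drawn genes with an adjusted p under 0.05; 121 genes with a group at 0 counts, 4 of them called, and 1 called gene beyond 6 on the log2 scale are left out.

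Among genes with an official symbol and a mean of at least 5 CPM, the largest rise was in Tymp, thymidine phosphorylase. It went from 1.83 ± 0.119 to 15.5 ± 0.972 CPM (SD, n = 2 each), 8.46-fold (adjusted p = 0.00373 by edgeR, Benjamini-Hochberg). Svbp, the partner of the tubulin-trimming vasohibins, rose 3.62-fold, Golph3l 3.28-fold, Szrd1 3.01-fold, Ccl6 2.93-fold and Trim26 2.83-fold. Cst7, a cysteine protease inhibitor, rose 2.65-fold and Abcg2, an efflux transporter, 2.47-fold. In the other direction Usp50, a ubiquitin-specific peptidase-like gene, had 677 and 723 counts in the control libraries and 0 in both knockdown libraries, at least 59.9-fold lower against a floor of 12 counts per library. Pde3b, a cyclic nucleotide phosphodiesterase, fell by 1.86 ± 0.22 and Ddit4, an inhibitor of mTORC1 signalling, by 1.79 ± 0.15 on the log2 scale (SE). Capn2 fell by 1.62 ± 0.17, Fxyd2 by 1.59 ± 0.21 and Kif3c, a kinesin, by 1.43 ± 0.18. Genes without an official symbol (Gm numbers and Rik names) were left out of this ranking, among them the processed pseudogene Gm6430. It had the lowest adjusted p of all genes (0.00117 by edgeR, Benjamini-Hochberg) and fell from 58.3 ± 7.41 to 4.21 ± 0.518 CPM. Tymp, Golph3l and Usp50 overlap another gene model on the same strand, and Szrd1, Ccl6, Trim26 and Kif3c one on the opposite strand, so how reads were assigned makes their values uncertain. Without edgeR's robust option, 28 of the 32 changed genes taken by the naming rule lost their call. Among them were Nos2, Igf1, Acod1 and C3 (adjusted p = 0.0634, 0.0563, 0.0563 and 0.0573), and Ddit4 and Ccl6 (0.0563 and 0.0530). Tymp, Usp50, C1qb and C1qc still passed (adjusted p = 0.0247, 0.0364, 0.0443 and 0.0364).

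**Figure D2:**
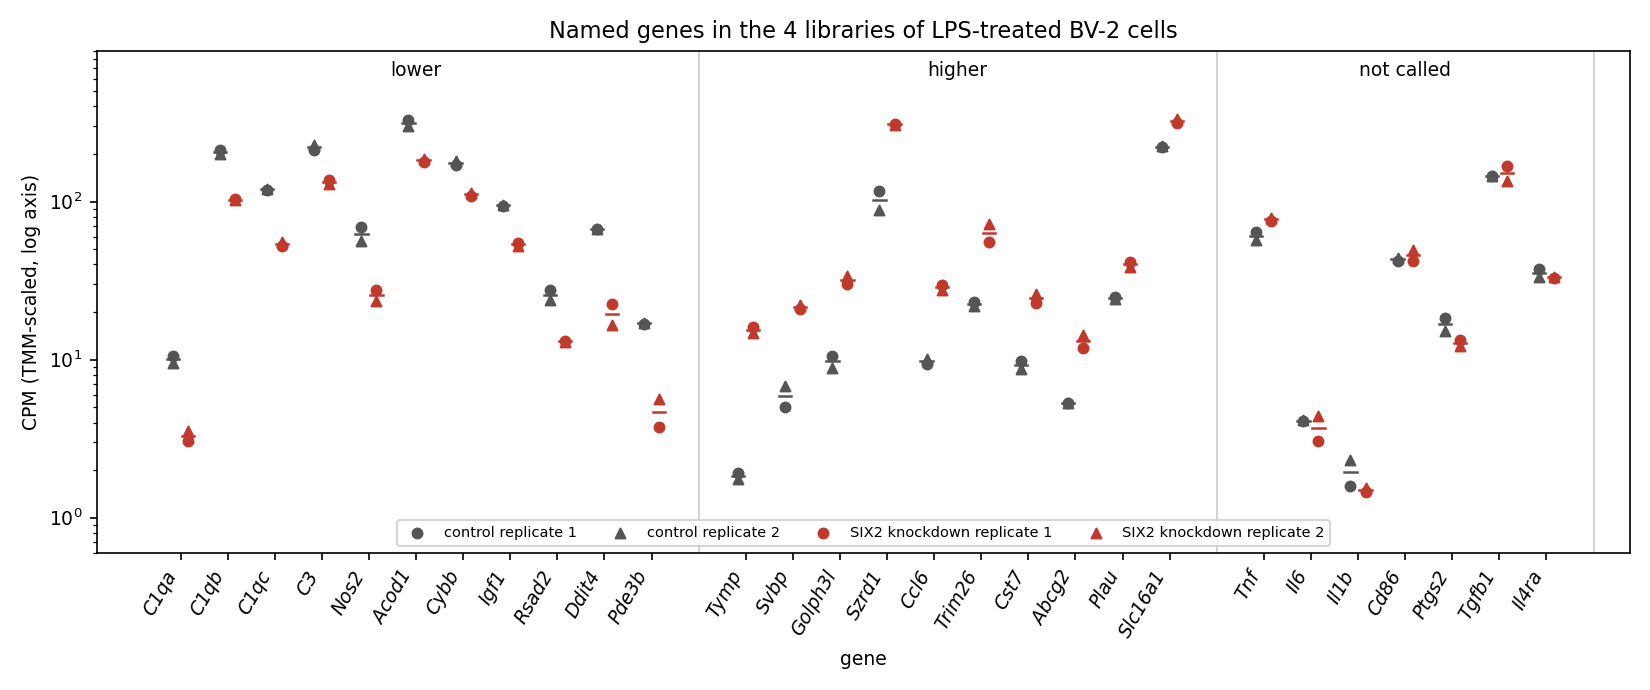
The vertical axis gives CPM after TMM scaling (log axis) for the genes named along the horizontal axis, grouped by whether they were lower, higher or not called. Circles and triangles are replicates 1 and 2, grey for control and red for knockdown, and short lines are group means.

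Of the pro-inflammatory (M1-type) genes, 25 were tested and 5 fell, none rose and 20 did not pass over all genes. Adjusted over the list alone, 5 fell and 1 rose, which was Tnf. Acod1, the itaconate-producing enzyme of LPS-treated macrophages, fell from 315 ± 21.4 to 182 ± 4.47 CPM (adjusted p = 0.0152 by edgeR, Benjamini-Hochberg), and Nos2 fell by 1.29 ± 0.14 on the log2 scale (SE, adjusted p = 0.0159). Cybb, the catalytic subunit of the phagocyte NADPH oxidase, fell by 0.65 ± 0.08 (adjusted p = 0.0183), and the other members that fell were Socs3 and Fcgr1. Tnf had 60.8 ± 4.96 CPM in control and 77.4 ± 2.23 CPM in knockdown libraries (adjusted p = 0.171 over all genes, 0.0301 over the list alone). Il6 had 4.09 ± 0.0420 and 3.72 ± 0.947 CPM, Ptgs2 16.9 ± 2.26 and 12.8 ± 0.730, and Cd86 43.0 ± 1.02 and 45.6 ± 5.39, none of which passed. Il1b, at 1.96 CPM in control libraries, had a log2 fold change of -0.38 ± 0.39 and did not pass either. The list as a set had a median log2 fold change of -0.14 and was not called by camera (adjusted p = 0.145, and 0.630 with an estimated correlation). It was called lower in 4 of 17 other settings, among them DESeq2's statistics (adjusted p = 4.7e-05).

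The alternative-activation (M2-type) list, the one nearest to the question in the series title, held 25 tested genes, of which 1 fell, 0 rose and 24 did not pass. The counts were the same when adjusted over the list alone. The gene that fell was Igf1 (chromosome 10, 87858265 to 87937042, plus strand), a trophic factor made by microglia, by 0.82 ± 0.08 on the log2 scale (SE, adjusted p = 0.0152 by edgeR, Benjamini-Hochberg). The classical markers Arg1, Mrc1 and Chil3 had low counts that differed between replicates: Arg1 had 43 and 10 counts in control and 4 and 76 in knockdown libraries, Mrc1 43 and 12 against 4 and 12, and Chil3 161 and 98 against 50 and 0. None of the 3 passed. Il10 had 1.34 ± 0.0679 and 0.914 ± 0.444 CPM. The receptor gene Il4ra had 35.4 ± 2.65 and 33.2 ± 0.411 CPM and Tgfb1 145 ± 0.978 and 152 ± 22.9 CPM. Across all tested genes, the median log2 fold change was -0.26 under 1 CPM, -0.11 from 1 to 5 CPM and 0.03 from 20 to 100 CPM. This list held 5 genes under 1 CPM, and whether its shift goes beyond that general one was not tested. As a set the list lay lower by camera (median log2 fold change -0.30, adjusted p = 0.0311), and adjusted p = 0.630 with an estimated correlation. The call was also lost without control replicate 1 (adjusted p = 0.255) and without knockdown replicate 2 (0.147).

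Type I interferon response genes held 1 that fell among 39 tested, and 2 when adjusted over the list alone. Rsad2, the antiviral protein viperin, fell by 0.98 ± 0.13 on the log2 scale (SE, adjusted p = 0.0318 by edgeR, Benjamini-Hochberg), from 25.8 ± 2.78 to 13.1 ± 0.213 CPM. The list-alone addition was Cmpk2, a nucleotide kinase (log2 fold change -1.08 ± 0.19). In all, 31 of the 39 fitted changes were below 0, with a median of -0.30. Camera called the list lower (adjusted p = 0.00047), with adjusted p = 0.630 with an estimated correlation. The list held 9 genes under 1 CPM, and 2 of its genes had a group at 0. Whether its shift goes beyond the general one of low-expressed genes was not tested. Of TLR4 and NF-kB signalling genes, the receptor and its cascade, 32 were tested and 0 passed over all genes by edgeR, with 1 higher and 5 lower at an unadjusted p of 0.05. Adjusted over the list alone 2 fell, Nfkb2 and Tnfaip3. Nfkb1 had 184 ± 9.29 and 169 ± 14.3 CPM and Tnip1 174 ± 7.40 and 159 ± 16.9 CPM, and camera gave an adjusted p of 0.327. The receptor gene Tlr4 had 31.7 ± 1.19 CPM in control and 18.3 ± 20.1 CPM in knockdown libraries. It did not pass, and its knockdown libraries differed widely.

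For the lists tied to exosomes and microRNA, none of the genes passed over all genes. Of 33 genes of extracellular vesicle biogenesis and release, 0 passed over all genes, and adjusted over the list alone Ykt6 rose while Anxa6 and Vps28 fell. Hspa8 had 2258 ± 506 and 2255 ± 338 CPM and Hsp90aa1 2022 ± 213 and 2010 ± 80.3 CPM, and camera gave an adjusted p of 0.978. Of 26 genes of microRNA processing and sorting, 0 passed over all genes and 0 when adjusted over the list alone (camera adjusted p = 0.224). Hnrnpa2b1, which sorts microRNA into vesicles, had 1316 ± 190 and 1468 ± 44.0 CPM and Hnrnpa1 1249 ± 21.8 and 1348 ± 39.9 CPM. Of 24 neurotrophic and growth factor genes, 1 fell in both countings, which was Igf1. That list's median was 0.01, its mean -0.55 (-0.01 with 2 genes at 0 in a group set to their bounds) and camera's direction lower (adjusted p = 0.579), and 11 of its genes lay under 1 CPM. Among 21 Wnt pathway genes 0 passed in either counting, with Ctnnb1 at 674 ± 39.1 and 706 ± 6.76 CPM and Lrp5 at 132 ± 2.84 and 127 ± 11.6 CPM. The dopaminergic and Parkinson's disease list held 22 tested genes and 0 passed in either counting, with Gpnmb at 1861 ± 151 and 1934 ± 26.8 CPM and Vps35 at 309 ± 3.90 and 353 ± 30.8 CPM. Its median was -0.03 while camera's direction was higher (adjusted p = 0.755). The fry test, which asks whether a list differs from no change rather than from other genes, called it lower (adjusted p = 0.0192).

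Genes of microglial identity and of complement included several that fell. Of 20 homeostatic microglia genes, 6 fell and 0 rose over all genes, against 9 and 1 when adjusted over the list alone. Beside the C1q genes, those that fell included Csf1r, the receptor microglia need for survival, and Aif1, which encodes the marker protein IBA1. The list's median was -0.38 and camera called it lower (adjusted p = 0.000442), with adjusted p = 0.630 with an estimated correlation. This list and the complement list each held 4 genes under 1 CPM. Whether their shifts go beyond the general one of low-expressed genes was not tested. Of 22 complement and Fc receptor genes, 5 fell and 0 rose over all genes, against 10 and 2 when adjusted over the list alone. C3, the central complement component, fell by 0.73 ± 0.08 on the log2 scale (SE, adjusted p = 0.0152 by edgeR, Benjamini-Hochberg), from 220 ± 10.5 to 133 ± 5.52 CPM. That list's median was -0.27 (camera adjusted p = 0.00173), with adjusted p = 0.630 with an estimated correlation, 0.0959 without control replicate 2 and 0.119 without knockdown replicate 1.

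The disease-associated microglia and lipid handling list went both ways, with 2 of 27 genes higher and 2 lower over all genes and 5 and 3 when adjusted over the list alone. Ccl6 and Cst7 rose, while Fabp4 and Fabp5, fatty acid binding proteins, fell, with Fabp4 going from 98.8 ± 8.20 to 63.4 ± 1.94 CPM (adjusted p = 0.0385 by edgeR, Benjamini-Hochberg). Camera gave the list an adjusted p of 0.375. Of 22 MHC and antigen presentation genes 0 passed in either counting, with Calr at 1310 ± 44.6 and 1302 ± 42.4 CPM and B2m at 740 ± 42.8 and 726 ± 24.7 CPM. Its median was -0.01 and its mean 0.02 (camera adjusted p = 0.566). Of 20 inflammasome and pyroptosis genes 0 passed in either counting, with Txnip at 98.3 ± 3.95 and 125 ± 13.7 CPM and P2rx7 at 87.6 ± 38.9 and 66.3 ± 2.97 CPM. Of 22 matrix metalloproteinase and adhesion genes, 1 rose over all genes, against 2 that rose and 2 that fell when adjusted over the list alone. It was Plau, the urokinase plasminogen activator, from 24.5 ± 0.406 to 40.1 ± 1.96 CPM (adjusted p = 0.0423).

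**Figure D3:**
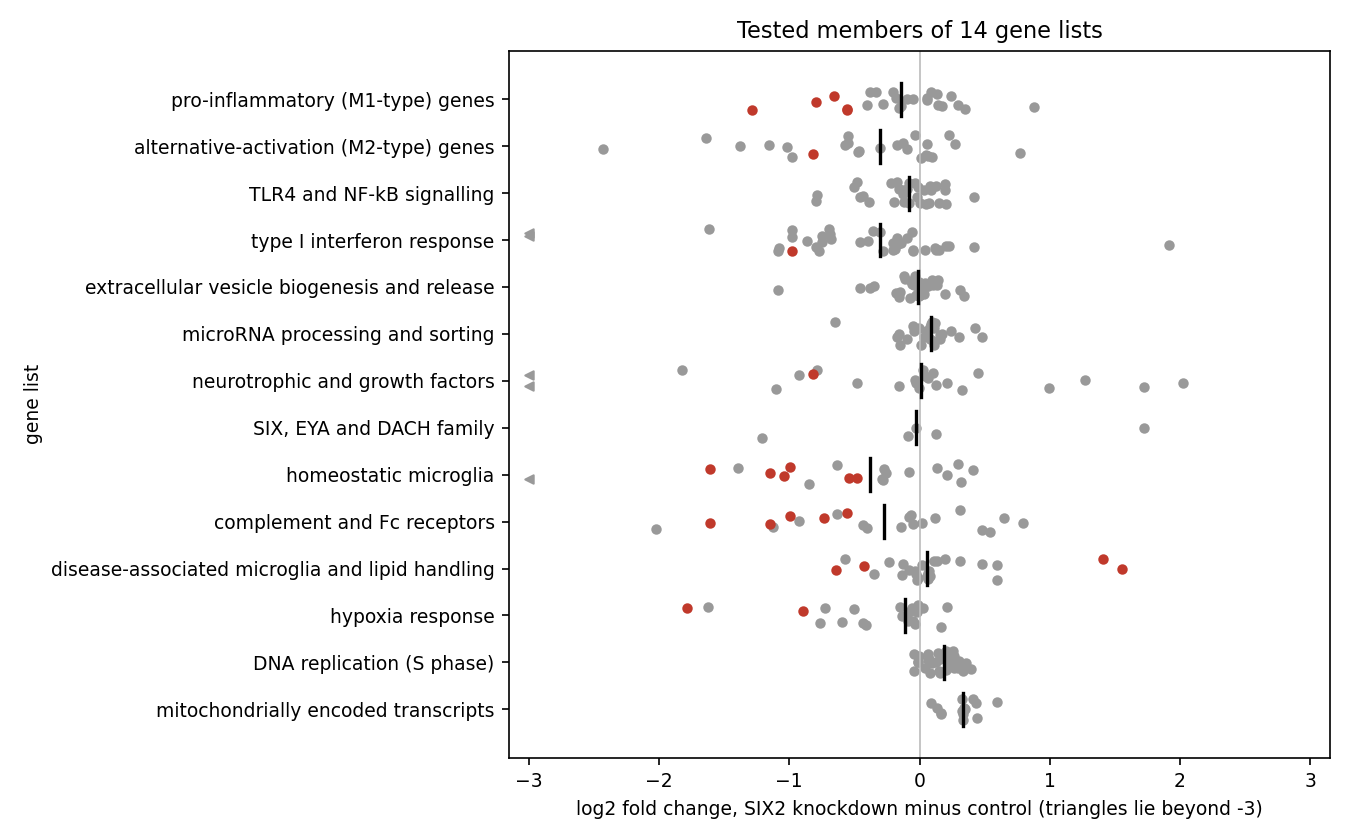
The horizontal axis gives the log2 fold change, knockdown minus control, of each tested member of 14 gene lists, which are set along the vertical axis. Each point is 1 gene, red where its adjusted p over all genes is under 0.05, black lines are list medians, and 5 members beyond -3 are drawn as triangles at the edge.

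Of 22 hypoxia response genes 2 fell and 20 did not pass over all genes, and 5 fell when adjusted over the list alone. Ddit4 fell from 67.4 ± 0.150 to 19.5 ± 4.05 CPM and Ndrg1 from 43.4 ± 3.40 to 23.3 ± 0.820 CPM (adjusted p = 0.0145 and 0.0226 by edgeR, Benjamini-Hochberg). Camera called the list lower (median -0.11, adjusted p = 0.00173), with adjusted p = 0.630 with an estimated correlation. Of 26 NRF2 oxidative stress genes, Me1 rose, from 28.1 ± 0.933 to 44.7 ± 2.81 CPM, and Sod2, the mitochondrial superoxide dismutase, fell, from 384 ± 18.9 to 278 ± 1.91 CPM. Adjusted over the list alone, 2 rose and 1 fell. Of 29 unfolded protein and integrated stress response genes, 1 fell in both countings, Herpud1, by 0.58 ± 0.08 on the log2 scale (SE, adjusted p = 0.0299). Of 22 glycolysis genes, 1 rose in both countings, the lactate transporter gene Slc16a1, from 223 ± 3.66 to 324 ± 12.1 CPM (adjusted p = 0.0241). Of 23 cholesterol synthesis and uptake genes 0 passed over all genes and 2 fell when adjusted over the list alone, with Fdps at 329 ± 24.2 and 281 ± 7.57 CPM and Srebf2 at 278 ± 63.4 and 268 ± 51.4 CPM. Of 27 immediate early and AP-1 genes 0 passed over all genes, against 2 that rose and 1 that fell over the list alone, with Jund at 118 ± 1.18 and 123 ± 15.3 CPM and Junb at 112 ± 0.649 and 106 ± 3.83 CPM. That list's median was -0.01 and its mean 0.02. Camera did not call the NRF2, unfolded protein, cholesterol, glycolysis or AP-1 lists (adjusted p = 0.287, 0.173, 0.190, 0.579 and 0.724).

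Of the 34 S phase genes, which act in DNA replication, 0 passed over all genes, and 8 rose when adjusted over the list alone, with a median log2 fold change of 0.19 and 29 fitted values above 0. By edgeR 14 of them reached an unadjusted p of 0.05. Pcna, the replication clamp, had 524 ± 6.67 and 627 ± 55.5 CPM and Rrm1 453 ± 46.9 and 450 ± 26.3 CPM. Camera called the list higher (adjusted p = 4.83e-05), with adjusted p = 0.630 with an estimated correlation. Of 36 mitosis genes 0 passed in either counting (camera adjusted p = 0.165), with Mki67 at 519 ± 15.7 and 553 ± 9.08 CPM and Top2a at 373 ± 34.0 and 396 ± 6.64 CPM. The list of 31 p53 target and apoptosis genes was not called by camera (adjusted p = 0.595, direction lower), with a median of -0.07 and a mean of 0.003. Of 15 histone genes 1 fell over all genes and 2 over the list alone, the first being H3f3a, from 768 ± 3.67 to 518 ± 26.3 CPM (adjusted p = 0.0223 by edgeR, Benjamini-Hochberg). Reads shared with near-identical copies of H3f3a could affect that value and were not tested.

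Of 15 mitochondrially encoded transcripts 0 passed over all genes and 5 rose when adjusted over the list alone. All 15 fitted values lay above 0, with a median of 0.33. The most abundant were mt-Nd1 at 4408 ± 306 and 5975 ± 703 CPM and mt-Co1 at 12947 ± 1303 and 13797 ± 1862 CPM. Camera called the list higher (adjusted p = 0.000957), with adjusted p = 0.788 with an estimated correlation and 0.196 without knockdown replicate 2. That library had the largest share of counts in mitochondrial genes, 4.94%, against 3.95% in knockdown replicate 1 and 3.69% and 3.98% in the controls. Of 36 nuclear genes of oxidative phosphorylation and 52 cytosolic ribosomal protein genes, 0 passed in either counting (camera adjusted p = 0.595 and 0.188). Atp5b had 1909 ± 74.2 and 1929 ± 4.83 CPM, Rplp0 4000 ± 368 and 3839 ± 194, and Rpl8 2487 ± 46.9 and 2442 ± 125. Atp5a1 had a log2 fold change of -0.08 ± 0.09 (SE).

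Markers of other cell types did not pass for any gene over all genes. Of 14 neuronal markers 9 lay under 1 CPM, the median log2 fold change was -1.95, and camera called the list lower (adjusted p = 0.0454), with adjusted p = 0.788 with an estimated correlation. It kept that call in 5 of 16 other settings. For many of its members the SD of the knockdown libraries was larger than their mean, so those libraries differed widely. Snap25 and Syt1 had 2.42 ± 0.532 and 1.80 ± 0.471 CPM in control libraries. In knockdown libraries they had 0.473 ± 0.668 and 0.466 ± 0.659 CPM. With 2 libraries, an SD that large means that a knockdown library was at 0. The list's most abundant members pointed the other way, with Nefh at 157 ± 2.73 and 182 ± 3.43 CPM and Syn1 at 13.6 ± 0.622 and 17.7 ± 2.25 CPM. Of 7 astrocyte markers 4 lay under 1 CPM, and camera called the list lower (median -1.67, or -1.61 with a gene at 0 set to its bound, adjusted p = 0.00173), with adjusted p = 0.630 with an estimated correlation. Aldoc had 25.4 ± 1.87 and 24.8 ± 2.22 CPM and Gja1 2.89 ± 0.0434 and 1.56 ± 0.198 CPM. The 6 oligodendrocyte lineage and 5 endothelial markers were not called (camera adjusted p = 0.145 and 0.501), with Cnp at 27.0 ± 2.57 and 26.5 ± 2.11, Mbp at 8.96 ± 0.475 and 2.04 ± 2.80, Kdr at 221 ± 1.56 and 222 ± 8.83 and Flt1 at 143 ± 4.68 and 163 ± 2.90 CPM. Mbp had 658 and 575 counts in the control libraries, 298 in knockdown replicate 1 and 4 in knockdown replicate 2. Fewer than 5 fibroblast and lymphocyte markers were tested, too few for a set test. Acta2 had 4.95 ± 0.782 and 3.56 ± 0.841 CPM, Thy1 0.961 ± 0.173 and 0.155 ± 0.220, and Lck 3.70 ± 0.833 and 4.37 ± 0.617. Thy1 had 64 and 67 counts in the control libraries, 23 in knockdown replicate 1 and 0 in knockdown replicate 2. The fall in Mbp and Thy1 was thus largest in knockdown replicate 2. Cd79b, a B cell receptor chain, had 7.20 ± 0.574 and 3.88 ± 1.11 CPM and was the 1 lymphocyte gene that fell over the list alone. Knockdown replicate 2 also had the fewest genes with a count, 17924, against 18785 in knockdown replicate 1 and 19399 and 18778 in the controls.

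Annotation terms were tested for the changed genes, higher and lower separately. Of 6840 tests 7 passed a Benjamini-Hochberg adjusted p of 0.05 by the one-sided Fisher exact test, all for genes lower in knockdown libraries. The complement activation, classical pathway term held 4 of the 80 lower genes with a term (C1qa, C1qb, C1qc and C3), against 0.0849 by chance (adjusted p = 0.00394). The Staphylococcus aureus infection pathway held those 4 and Fcgr1 (adjusted p = 0.00394), and the pertussis pathway held 6 genes, among them those 4 and Nos2 (adjusted p = 0.00407). Immune system process held 11 genes, among them the C1q genes, C3, Csf1r, Rsad2 and the macrophage scavenger receptor gene Marco (adjusted p = 0.0170). Response to bacterium held C3, Fabp4, Fcgr1, Hp, Nos2 and Saa3 (adjusted p = 0.0433). The remaining terms were systemic lupus erythematosus and collagen trimer (adjusted p = 0.0255 and 0.0301), each holding the C1q genes. Every term that passed, except response to bacterium, held the adjacent C1q genes, so these terms are not separate findings. The number of terms fell to 0 without control replicate 1 and without knockdown replicate 2 and to 1 without control replicate 2.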

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

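Counts divided by 4, the newer dispersion method and the set without overlapping genes and pseudogenes were chosen after the data were seen, and the other settings before. All 150 changed genes kept their direction in the 17 other fits wherever they were tested (116 without overlapping genes, 144 with the stricter filter). Those fits reused the libraries that picked the genes, so this was not a separate check. Most of the genes called with 1 library left out were not among the 150. The count stayed within 1.5 times 150 with RLE factors (145), library totals (138), the stricter filter (161), counts divided by 4 (166) and the newer dispersion method (162). Otherwise genes changed, SIX2 knockdown against control, genes higher in knockdown, genes lower in knockdown and genes changed at least 2-fold (150, 64, 86 and 55) were 806, 393, 413 and 199 with DESeq2, 65, 32, 33 and 29 with limma-voom, 7, 2, 5 and 6 without the robust option, 3, 1, 2 and 3 with log2(FPKM + 1) and the same 3, 1, 2 and 3 with log2(FPKM + 0.1), and 7, 2, 5 and 6 at an adjusted p under 0.01. With no filter on low counts 297 changed, 141 higher and 156 lower, and without overlapping genes and pseudogenes 243, 97 higher and 146 lower. Leaving out each library gave 41 to 112 changed, 20 to 47 higher, 20 to 65 lower and 38 to 87 at least 2-fold, with the lone library assumed to vary like the other group. The replicate block, which uses numbers that pair nothing in the labels (correlation of deviations 0.0486 over 2 pairs), left 0 changed, 0 higher, 0 lower, 0 at least 2-fold and 0 terms, while 2055 genes had an unadjusted p under 0.05. The cause was not tested for any of these differences, except that fewer genes or samples were tested where a setting removes them.

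The list of pro-inflammatory (M1-type) genes, not called in the main analysis, was called lower with DESeq2 (adjusted p = 4.7e-05), the stricter filter (0.0064), log2(FPKM + 1) (0.046) and camera on voom-weighted values (0.0192). A further primary list: alternative-activation (M2-type) genes, lost its call with the stricter filter (0.0911), without overlapping genes and pseudogenes (0.0507), with an estimated correlation (0.630) and by fry (0.0501), and ranged from 0.0286 to 0.255 leaving out each library. The interferon list lost its call with an estimated correlation (0.630) and by fry (0.0501). The Parkinson's disease list, uncalled and higher by camera, was called lower by fry (0.0192), which tests against no change rather than against other genes, so that no call was reversed. Annotation terms (7) numbered 1 with 2-fold genes only, 2 with DESeq2, 4 with no filter, 2 with limma-voom, 1 without the robust option, 0 and 0 with the FPKM settings, 2 without overlapping genes and pseudogenes, and 0 to 10 leaving out each library. Among the other lists 382 of 419 pairs of list and setting were the same, 29 weaker, 7 stronger and 1, that of fry, opposite in direction. Six2 had 0 counts in all 4 libraries, and limited depth could not be told from a lack of expression.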

Other observations

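The genes in the next 2 paragraphs were chosen after their values were seen, and so were 4 of the 6 tests that follow; the tests of sequencing depth and of knockdown replicate 2 alone were written before. Several genes outside the fixed lists fell in the knockdown libraries. Marco, a scavenger receptor, fell from 166 ± 1.92 to 72.7 ± 8.15 CPM (SD, n = 2 each, adjusted p = 0.0123 by edgeR, Benjamini-Hochberg), and Lyz2, lysozyme, from 332 ± 14.8 to 166 ± 23.3 CPM. Adgre1, which encodes the F4/80 antigen, fell from 264 ± 12.2 to 171 ± 6.78 CPM. The acute phase genes Saa3 and Hp fell from 1595 ± 205 to 778 ± 42.6 and from 43.5 ± 0.117 to 18.8 ± 0.717 CPM. Kctd12 fell from 197 ± 0.174 to 80.1 ± 0.681 CPM.

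Genes that rose included Ccl9, a chemokine gene, from 39.7 ± 4.48 to 88.2 ± 9.93 CPM, and the cell cycle genes Ccnd2, cyclin D2, from 89.3 ± 5.36 to 157 ± 3.27 CPM, and Skp2, from 56.6 ± 1.83 to 86.7 ± 2.47 CPM (adjusted p = 0.0152, 0.0152 and 0.0299 by edgeR, Benjamini-Hochberg). Cdkn2b, an inhibitor of the cell cycle, rose from 2.06 ± 0.00327 to 6.62 ± 0.239 CPM.

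The homeostatic, complement and M1-type lists held 12 genes that fell, and these, among them C1qa, C1qb, C1qc, C3, Csf1r, Acod1, Nos2 and Cybb, had a median log2 fold change of -0.76, from -1.61 to -0.48. The median of 8906 genes with a mean of at least 10 CPM was 0.0238, a gap of 0.78. These genes were picked because they fell, so a gap was fixed by that choice and cannot decide on library scaling. Scaling moves all genes alike, so it leaves the size of the gap as it is. With library totals alone the median of all genes was -0.04. A weaker LPS response as a whole could not be told from a narrower one, since the M1-type list had a median of -0.14 and an upper quartile of 0.13, and no untreated library was compared. A difference in growth could not be told either, with the mitosis list at a median of 0.0634 (camera adjusted p = 0.165) and the S phase list called higher (4.83e-05, and adjusted p = 0.630 with an estimated correlation). An effect of SIX2 itself stays open, because Six2 was at 0 counts in all 4 libraries and any difference between the cultures coincides with the groups.

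Of the 16 changed genes with a fold of at least 4, 10 (62.5%) overlap another gene model on the same strand or are pseudogenes, against 24 of 134 other changed genes (17.9%) and 26.8% of all tested genes (two-sided Fisher exact p = 0.00032). That test was written after the pattern was seen and restates it, so shared reads stay open. Most of the overlapping models moved opposite to the changed gene, by different amounts. Tymp went from 1.93 and 1.77 to 16.1 and 14.6 CPM (not TMM-scaled) while Sco2, which overlaps it, went from 17.7 and 19.9 to 8.19 and 11.4, but Usp50 went from 8.95 and 11.9 to 0 while Gm10774, which overlaps it, reached at most 2.96. Of 2 overlapping Pakap models 1 went from 0 and 0 to 3.09 and 2.35 while the other went down to 0.228 and 0.763, and Gm20633 rose from 0.687 and 0.870 to 3.29 and 4.16 with its overlapping model, Gm47313, at most at 0.0268 in any library. Tubb2b, Fam57b, Ptgfrn, Armh2, Pdcd1 and 9130221H12Rik overlap no such model, near-identical copies of them were not tested, and real changes were not excluded.

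Fewer genes were detected in both knockdown libraries at equal depth. At full depth knockdown replicate 1 had 18785 genes with a count, against 18778 in control replicate 2. Thinned to equal depth (20 thinnings), knockdown replicate 2 had 16998 genes and replicate 1 had 17560, against 17955 and 18130 in the controls (replicate 2 minus the lower control -957), so sequencing depth does not account for the gap. The gap was larger in knockdown replicate 2 but not confined to it. With 0.1 CPM added before the log, genes with a mean under 1 CPM had a median log2 fold change of -0.20 with all libraries. That median was -0.17 without knockdown replicate 2 and -0.34 without control replicate 1, so how far 1 library sets it stays open. The edgeR fit gave a median of -0.26 for genes under 1 CPM with all libraries. RNA quality, traces of RNA from other cell types and a biological loss of low-expressed genes were not tested as sources of the gap.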
